A study of Mus musculus with 10 samples.

How the data were processed

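Gene expression and newly made RNA were measured in 10 RNA-seq libraries of NIH-3T3 cells, 2 per group, described per the labels as untreated, uridine, 4sU without conversion, 4sU with SLAM chemistry and 4sU with TUC chemistry. 1 deposited table covers 17053 Ensembl genes. Per the submitters' processing notes, cutadapt (version not given), Bowtie2 2.3.0 and STAR 2.7.10b were used. The genome build, the annotation, the counting tool, the strand setting and the tool that estimated new RNA are not given in the sources used here. Expected counts of reads per gene and library were deposited without scaling between libraries, per the file headers and values, with 24.8 to 30.3% of genes per library holding a count that is not whole, so reads shared by genes appear to be split. A fraction between 0 and 1 was deposited per gene for 8 libraries as a posterior mode with lower and upper bounds, per the file headers. The headers do not name the quantity, which is taken here as the new-to-total RNA ratio (NTR), since it lies near 0 in libraries without conversion. A gene length in bases was deposited, per the file headers, without saying which length it is. Of the values per library, 24 columns (the mean and shape values of the NTR estimate) were not used. No conversion counts were used, so the planned conversion rate per library was not computed.

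Groups and replicate letters were taken from the sample titles. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicates differed by more than sampling noise (chi-square per degree of freedom 37.5 to 76.6 between letters of a group), and 1 pair across groups, untreated A and uridine A, gave 4.32. Gene totals ranged from 27094222 to 33785682 counts per library, and the 10 most abundant genes took 4.8 to 5.74% of them. 91.2% of symbols (15548 genes) were found in the names table of RefSeq's GRCm38.p6 assembly, which was used for names and neighbours only, and 25 symbols belonged to more than 1 gene. The table listed 0 mitochondrially encoded genes.

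Expected counts were rounded to whole numbers. Genes passing edgeR's filterByExpr (12218) were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, R 4.3.3) in 1 fit over all 10 libraries with a term per group, so that groups of 2 share an estimate of the spread. Adjusted p (Benjamini-Hochberg) under 0.05 was the threshold in 8 comparisons. CPM are edgeR's counts scaled to a common library total with TMM factors. limma 3.58.1 camera with a preset correlation of 0.01 tested 23 of 25 gene lists on log2 CPM (prior count 2), adjusted over the lists of a comparison, with an estimated correlation and fry beside it. The mitochondrially encoded list (0 of 15 in the table) and the epithelial list (5 of 10 in the table, 0 past the filter) were not tested, and the smallest list tested had 3 genes. The lists were p53 targets, immediate-early genes, short-lived regulators, ribosome biogenesis, ribosomal proteins, integrated stress response, heat shock, NRF2 targets, interferon response, NF-kB inflammatory genes, oxidative phosphorylation, glycolysis, fibroblast identity, actin and SRF targets, histones, G1/S, G2/M, pyrimidine metabolism, cholesterol synthesis, nuclear noncoding RNAs and markers of other cell types.

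Design, lists, main tests, the rule for named genes and most alternatives were fixed before the data were examined. That rule took, per comparison, the 8 genes with the largest and the 8 with the smallest log2 fold change among called genes with a CPM of 10 or more in the higher group, non-overlapping libraries and a symbol that is no predicted, clone or pseudogene name. It added up to 4 called members of each list past the threshold and 7 reference genes (Actb, Gapdh, Myc, Fos, Jun, Cdkn1a, Mdm2). For NTR it took the 8 highest and 8 lowest genes with 200 reads or more and up to 6 each way for the difference. The same rule applied to the fit with the letter as a block, requiring the same sign in both letters, was chosen after seeing the data.

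The letters A and B occur in every group, and the labels do not say what libraries of one letter share. They were taken to pair the libraries because the A minus B differences of any 2 groups correlated across genes (r 0.584 to 0.69 over 10 pairs of groups) and the second principal component (24.0% of variance, after 48.7% for the first) separated the letters, from 2.57 to 22.7 in A and from -26.9 to -1.96 in B. The common dispersion was 0.0187 without and 0.00195 with the letter as a block. The fit without the block is the main one because it was fixed as such.

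NTR was ranked as the mean of the SLAM libraries over 10232 genes with a mean of 100 reads or more, in 5 bins of 20% each. High minus low NTR per library was tested by a two-sided exact permutation of 6 against 4 libraries. Dropout was the share of new RNA lost at which the Spearman correlation across genes of the corrected log2 ratio to untreated with NTR became 0 (pseudocount 0.5). NTR of TUC and SLAM was compared with limma (trend) on logit NTR held 0.001 away from either end, over 9956 genes with 100 reads or more in each of 4 libraries. Intervals for counting error were not needed, since spread between libraries exceeded it.

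Alternatives fixed beforehand were DESeq2 1.42.0, RLE factors, library totals, no filter, a mean of 100 counts, only the 4 libraries of a comparison, the letter as a block, and leaving out each library. For NTR they were TUC values, the top 10%, minima of 200 and 500 reads and the untransformed scale. Alternatives chosen after seeing the data were the block combined with library totals, a count minimum, left-out libraries or an estimated correlation, the block on the NTR bins and on dropout, and ranking NTR within bins of gene length. Leaving out a library leaves 1 in its group, which is assumed to vary like the other groups.

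The tests were tested on simulated data for TUC against SLAM. Without a letter effect the edgeR fit recovered 43.3% of 1.5-fold, 89.6% of 2-fold and 100% of 4-fold changes over 12144 genes, with 4.32% false calls, and DESeq2 49.3, 88.1 and 100% with 12.6% false calls. With a letter effect (12151 genes) the fit without the block recovered 17.9% of 1.5-fold, 65.7% of 2-fold and 95.5% of 4-fold changes with 0 false calls, and the fit with it 98.5, 100 and 100% with 5.65% false calls. That simulated letter effect was the same in every group, with the noise of the blocked fit. The rates for the fit with the block therefore hold only where letters differ alike in all groups. A list of 40 genes shifted 1.3-fold had a camera p of 5.08e-15, and of 0.00025 with an estimated correlation. Its genes were drawn at random and varied independently, without a letter effect. The simulation therefore does not show whether camera with an estimated correlation can detect a shift in lists whose genes vary together. limma on logit NTR recovered 77.6% of shifts of 1 and 100% of shifts of 2 or 3 logits over 9956 genes. That simulation gave every gene the same noise, the median spread. Its rates therefore do not hold for genes of larger spread, such as many near an NTR of 1. In the data Rpusd2 differed by -2.96 ± 0.972 logits (SE) and did not pass (limma adjusted p = 0.435). Gspt2 passed at -3.07 ± 0.595 logits (limma adjusted p = 0.00205). A simulated dropout of 30% was estimated as 29.8%, in a simulation without a length effect, a letter effect or error in NTR. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6).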

Results

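RNA was sequenced from NIH-3T3 cells, an established mouse embryonic fibroblast line, in 10 libraries that fall into 5 groups of 2 replicates, named A and B. The groups were untreated cells, cells given 800 µM uridine for 2 h, and 3 groups given 800 µM 4-thiouridine (4sU) for 2 h. 4sU is a uridine analogue that cells build into the RNA they make while it is present. One 4sU group was sequenced without chemical conversion. In the SLAM group the 4sU was alkylated with iodoacetamide, and in the TUC group it was treated with osmium tetroxide and an ammonium salt, so that in both groups labelled positions can be read as T-to-C mismatches. The study asks about bias in quantification by these chemistries. Uridine and unconverted 4sU libraries were therefore set against untreated ones, each chemistry against unconverted 4sU libraries, and the chemistries against each other. Gene counts summed to 33225933 and 33785682 in untreated A and B, and to 27094222 in uridine A, the smallest library. The new-to-total RNA ratio (NTR), the share of a gene's RNA made during labelling, was given for 8 of the 10 libraries, all but the untreated ones.

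None of the 7 reference genes passed between uridine and untreated cells. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, stood at 87.4 ± 3.47 CPM (counts scaled to a common library total by edgeR; SD, n = 2) with uridine and 87.5 ± 2.56 without. Mdm2, the ubiquitin ligase that degrades p53, stood at 64.7 ± 5.83 and 63.6 ± 0.16 CPM, and Myc at 87.4 ± 8.39 and 88.2 ± 15.0 CPM. Actb and Gapdh, cytoskeletal and glycolytic reference genes, had log2 fold changes of -0.05 ± 0.118 and -0.004 ± 0.258 (SE), and Jun 0.03 ± 0.107. Fos, a low-count immediate-early gene, had the largest value of these (-0.32 ± 0.211), at 2.09 ± 0.437 CPM with uridine and 2.60 ± 0.363 without, and was lower in both letters. Of 12218 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against 46 at an unadjusted p under 0.05. DESeq2 also called 0, with 13 at an unadjusted p under 0.05. None of the 23 gene lists tested shifted, the smallest camera adjusted p being 0.696, although 5 lists passed higher without untreated A, 3 lower without untreated B, 4 lower without uridine A and 4 higher without uridine B, directions that follow the letter left unbalanced. 1 gene was called with the replicate letter as a block, Rps2-ps6, a ribosomal protein pseudogene chosen for mention after its values were seen. Its log2 fold change was 0.67 ± 0.098 (adjusted p = 0.0434), and its reads may not be separable from those of its parent gene. The block with library totals, or with a mean of 100 counts or more, called 0 genes. The call was kept without untreated B or uridine B and lost without untreated A or uridine A, each leaving 0 genes.

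Unconverted 4sU libraries differed from untreated ones most clearly in targets of p53, the transcription factor activated by DNA damage and nucleolar stress. Cdkn1a (ENSMUSG00000023067) rose from 87.5 ± 2.56 to 244.5 ± 0.899 CPM (SD, n = 2 each), a log2 fold change of 1.48 ± 0.078 (SE; adjusted p = 0.000797, edgeR quasi-likelihood with Benjamini-Hochberg). Btg2, an antiproliferative factor, rose by 1.21 ± 0.095, Sesn2, a stress-induced regulator of mTORC1, by 1.07 ± 0.107, and Phlda3, an inhibitor of AKT signalling, by 1.04 ± 0.098. Gtse1 and Psrc1, a pair of microtubule-binding proteins, rose by 0.90 ± 0.094 and 1.14 ± 0.133. Of the 26 p53 targets tested, these 6 rose and 0 fell over all genes tested, and 16 rose and 0 fell when adjusted over the list alone. The list's median log2 fold change was 0.49 (camera adjusted p = 4.95e-20, and adjusted p = 0.00472 with an estimated correlation). In the fit with the letter as a block 20 rose, 0 fell and 6 did not pass. That fit also called Mdm2, at 141.8 ± 16.7 against 63.6 ± 0.16 CPM (log2 fold change 1.15 ± 0.075, adjusted p = 5.38e-08, against adjusted p = 0.0593 without the block). It called Eda2r, a death receptor (1.61 ± 0.101), and Trp53inp1, a p53 cofactor (1.47 ± 0.086).

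**Figure D1:**
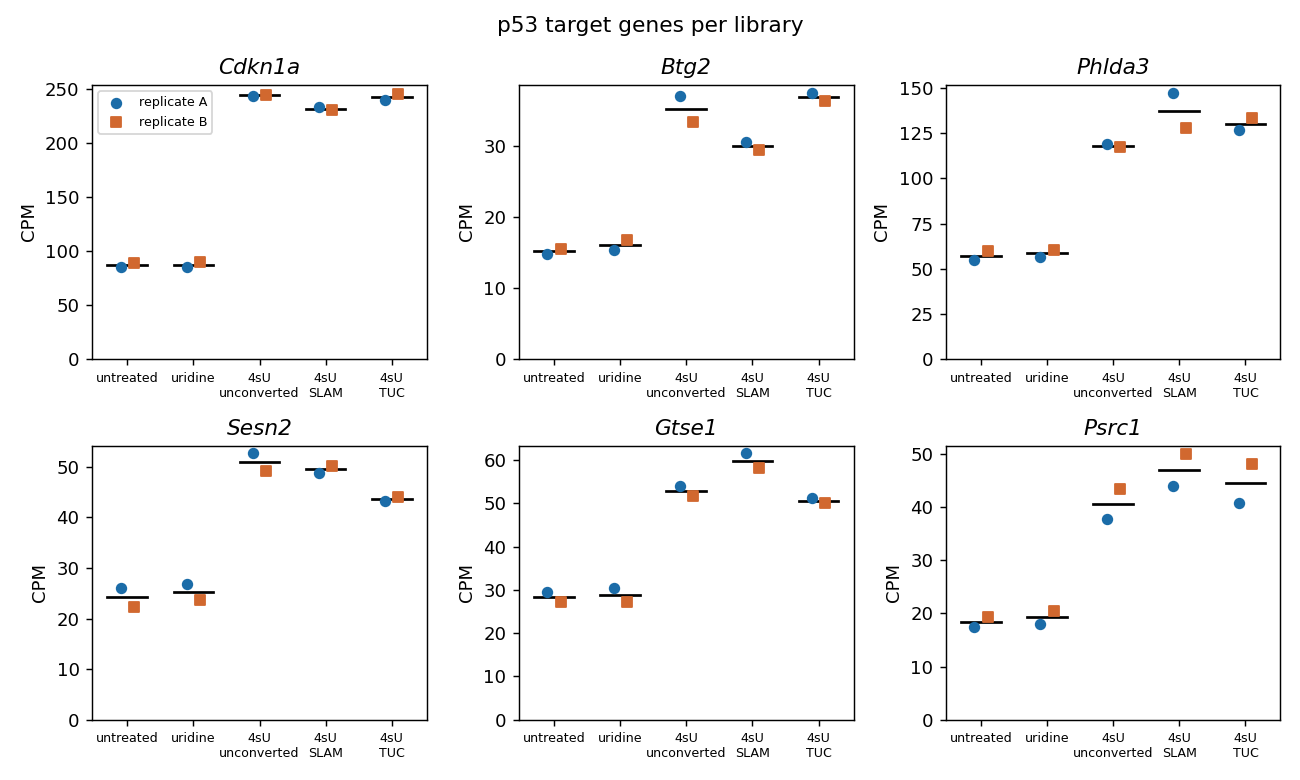
CPM of Cdkn1a, Btg2, Phlda3, Sesn2, Gtse1 and Psrc1 in the 5 groups; bars are group means and points are the 2 libraries of each group. Cdkn1a lay between 84.95 and 89.85 CPM in the 4 libraries without 4sU and between 231.0 and 246.1 CPM in the 6 libraries with it.

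Outside the p53 list, Ddias, an anti-apoptotic gene, rose by 1.00 ± 0.106 and Ptgs2, the inducible cyclooxygenase, rose from 567.6 ± 68.7 to 1029 ± 27.1 CPM (0.86 ± 0.112, adjusted p = 0.0442). Genes of mitosis were among those that fell. Ttk, a spindle checkpoint kinase, dropped from 22.5 ± 2.44 to 11.6 ± 0.29 CPM (log2 fold change -0.95 ± 0.114, adjusted p = 0.0256, edgeR quasi-likelihood). Aspm, a spindle pole protein, fell by 0.69 ± 0.092 and Ect2, which drives cytokinesis, by 0.64 ± 0.075. Map4k5 (-0.82), Ppp6r3 (-0.78), Nol10 (-0.69), Cul1 (-0.58) and Tex10 (-0.58) fell as well. In all, 11 genes were higher and 9 lower, with 1102 at an unadjusted p under 0.05. DESeq2 called 241 (37 higher, 204 lower). The fit with the letter as a block called 2432 (851 higher, 1581 lower), 206 of them past 1.5-fold. Among the lower ones were Rasa1, a Ras GTPase-activating protein (-1.10 ± 0.053), the helicase Dhx9 (-0.98 ± 0.132), the ubiquitin ligase Itch (-0.91), Lemd3 (-0.91), Fam208a (-0.91), Pik3c2a (-0.88) and Wdhd1 (-0.88). Without untreated A, untreated B or unconverted 4sU A the count fell to 2, and without unconverted 4sU B to 3. With the block it was 1056, 1996, 943 and 890 in the same order.

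The G2/M list fell, with a median of -0.07 over 24 genes (camera adjusted p = 0.0304, and adjusted p = 0.767 with an estimated correlation). Of its members 0 passed over all genes, 4 fell adjusted over the list alone, and 9 fell and 1 rose with the letter as a block. Those 9 included the mitotic kinesins Kif11 (-0.47) and Kif23 (-0.39), topoisomerase Top2a (-0.48) and the kinetochore gene Cenpf (-0.51). Ribosomal protein genes had a median of 0.21 (41 genes, camera adjusted p = 4.03e-05, and adjusted p = 0.767 with an estimated correlation). None passed over all genes or over the list alone, and 30 rose with the block, such as Rps2 (0.36), Rpl10a (0.32), Rps16 (0.27) and Rps20 (0.26). Many ribosomal protein genes have near-identical processed copies, so their counts are uncertain. Nuclear genes of oxidative phosphorylation had a median of 0.18 (32 genes, adjusted p = 6.33e-06, and adjusted p = 0.767 with an estimated correlation). There too 0 passed over all genes or over the list alone, and 14 rose with the block, among them Ndufb3 (0.29), Uqcr10 (0.25), Cox8a (0.25) and Cox7c (0.24).

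Immediate-early genes had a median of 0.10 and short-lived regulators of 0.09 (29 and 30 genes, both camera adjusted p = 0.0381, and adjusted p = 0.285 with an estimated correlation). Among immediate-early genes 1 member, Btg2, which is also in the p53 list, passed over all genes and over the list alone. With the block 6 rose and 1 fell, among them Dusp6 (0.32), Egr3 (0.28) and Ier3 (0.27). Short-lived regulators had 0 calls over all genes and 1 each way adjusted over the list alone. With the block 9 rose and 1 fell, including the kinases Plk3 (0.48) and Plk2 (0.30, also in the p53 list) and the EGFR inhibitor Errfi1 (0.44). The anti-apoptotic Mcl1 fell by 0.40. Replication-dependent histones had a median of 0.45 (10 genes, adjusted p = 0.0381, and adjusted p = 0.285 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. With the block that list's adjusted p was 0.0616, and its 1 called member was Hist1h1c (0.55). Jun (-0.03), Actb (0.05), Gapdh (0.21), Fos (0.30) and Myc (-0.18) did not pass.

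The other lists did not pass by camera. Medians and camera adjusted p were 0.07 and 0.122 for the integrated stress response, 0.11 and 0.0854 for fibroblast identity, and 0.08 and 0.0854 for actin and SRF targets. With the letter as a block the stress response list had an adjusted p of 0.0428 (6 higher, 3 lower) and fibroblast identity of 0.033 (6 higher, 1 lower). Both lost the call with the block and an estimated correlation (adjusted p = 0.533 each), and fibroblast identity passed by fry without the block (adjusted p = 0.0467). Ribosome biogenesis (-0.03, adjusted p = 0.24), NF-kB inflammatory genes (0.03, adjusted p = 0.24) and glycolysis (0.12, adjusted p = 0.24) did not shift, nor did NRF2 targets (0.13, adjusted p = 0.351) and interferon response genes (0.04, adjusted p = 0.351). Cholesterol synthesis (0.05, adjusted p = 0.198), pyrimidine metabolism (0.06, adjusted p = 0.198), G1/S replication genes (0.05, adjusted p = 0.395) and nuclear noncoding RNAs (0.17, adjusted p = 0.106) also stayed above the threshold. The heat shock list had a median of 0.07, a mean of 0.002 and a downward test (adjusted p = 0.768). Few markers of other cell types were measured: 3 endothelial (0.36, adjusted p = 0.383), 4 adipocyte or muscle (0.30, adjusted p = 0.122) and 3 macrophage genes, whose median of 0.03 and mean of -0.04 differ in sign (adjusted p = 0.895). Of 10 epithelial markers 5 were listed and 0 had enough counts to be tested.

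Against uridine, which controls for the added nucleoside, unconverted 4sU gave 12 higher and 19 lower genes, with 1237 at an unadjusted p under 0.05. Cdkn1a rose by 1.48 ± 0.078 (adjusted p = 0.000797, edgeR quasi-likelihood), Btg2 by 1.13, Psrc1 by 1.07, Sesn2 and Ddias by 1.01 each, Gtse1 by 0.88 and Ptgs2 by 0.80. Phlda3 rose from 58.5 ± 2.43 to 118.2 ± 1.3 CPM (SD, n = 2). Ttk fell by 0.96, Itch by 0.95, Slf1, which acts in DNA repair, by 0.94, the Holliday junction resolvase Gen1 by 0.91, Map4k5 by 0.85, Ppp6r3 by 0.78, Rbm34 by 0.71 and Nol10 by 0.70. Of 26 p53 targets 6 rose, 15 rose adjusted over the list alone and 18 with the letter as a block, and 0 fell. Their median was 0.46 (camera adjusted p = 1.19e-17, and adjusted p = 0.00642 with an estimated correlation). DESeq2 called 275 genes (40 higher, 235 lower) and the blocked fit 2412 (792 higher, 1620 lower). Mdm2 (1.13 ± 0.075), Trp53inp1 (1.56 ± 0.089) and Fos (0.63 ± 0.167) rose with the block, and Mcl1 (-0.47) and Rasa1 (-1.11) fell. The count fell to 1 without uridine A or uridine B and to 2 without unconverted 4sU A or unconverted 4sU B. With the block these were 1042, 969, 929 and 955.

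The other lists that passed against uridine lost the call with an estimated correlation. G2/M genes had a median of -0.08 over 24 genes (camera adjusted p = 0.0187, and adjusted p = 0.807 with an estimated correlation), with 0 called over all genes, 4 lower adjusted over the list alone and 8 lower with the block. Ribosomal protein genes had a median of 0.18 (adjusted p = 0.000711, and adjusted p = 0.807 with an estimated correlation) and oxidative phosphorylation genes of 0.17 (adjusted p = 8.83e-05, and adjusted p = 0.807 with an estimated correlation). In both 0 were called over all genes or over the list alone, and 20 and 9 rose with the block. Immediate-early genes had a median of 0.07 (adjusted p = 0.0471, and adjusted p = 0.364 with an estimated correlation), with 1, Btg2, called over all genes and over the list alone, and 6 higher and 1 lower with the block. Short-lived regulators had a median of 0.11 (adjusted p = 0.0184, and adjusted p = 0.253 with an estimated correlation), with 0 called over all genes, 1 lower adjusted over the list alone, and 11 higher and 1 lower with the block. Fibroblast identity genes passed by camera with the block (median 0.14, adjusted p = 0.00964, against adjusted p = 0.0764 without) and by fry without it (adjusted p = 0.0458), with 6 higher and 0 lower. With the block and an estimated correlation it lost the call (adjusted p = 0.565).

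SLAM conversion of 4sU RNA was followed by 40 higher and 2 lower genes against unconverted 4sU RNA. Fam122a rose from 3.60 ± 0.101 to 11.4 ± 0.101 CPM (SD, n = 2), a log2 fold change of 1.66 ± 0.182 (adjusted p = 0.0248, edgeR quasi-likelihood). Ccdc85b, a transcriptional repressor, rose from 18.7 ± 1.67 to 49.5 ± 0.948 CPM (1.40 ± 0.114, adjusted p = 0.0201). Cebpb, a bZIP transcription factor encoded by an intronless gene, rose by 0.94 ± 0.137, and Socs1, an inhibitor of cytokine signalling, by 0.87 ± 0.11. Zbed5 (1.25), Dpysl2 (0.77), Epn1 (0.72) and Btbd2 (0.68) also rose. Pggt1b, a subunit of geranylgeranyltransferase, fell by 0.92 ± 0.125. In the names table Fam122a lies within Pip5k1b and Ccdc85b overlaps Fosl1, and how reads of overlapping genes were assigned is not given, so these values are uncertain. Cdkn1a (-0.07 ± 0.076) did not pass in either fit. Mdm2 (-0.21 ± 0.167) did not pass without the letter as a block and fell with it (-0.21 ± 0.072, adjusted p = 0.0259).

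With the letter as a block, 5079 genes differed between SLAM and unconverted libraries (2443 higher, 2636 lower), 564 of them past 1.5-fold. Malat1, a nuclear long noncoding RNA, fell from 799.6 ± 456 to 266.8 ± 133 CPM in that fit (-1.56 ± 0.201, adjusted p = 2.71e-05, against adjusted p = 0.21 without the block). Zbed6, which lies within Zc3h11a, fell by 1.80 ± 0.205, Zfp871 by 1.29, Lcor by 1.27, Pdpr by 1.12, Tmppe by 1.08 and the copper transporter Atp7a by 1.04. Lnpep, an aminopeptidase, had a log2 fold change of -1.197. Fyb (0.99), Rsc1a1 (0.94), Ppp2r3d (0.90) and Kxd1 (0.90) rose. DESeq2 called 693 genes (360 higher, 333 lower), and 2284 lay at an unadjusted p under 0.05 in the fit without the block. In that fit the count fell to 0 when unconverted 4sU A, unconverted 4sU B, SLAM A or SLAM B was left out, with 1887, 1180, 1236 and 3353 at an unadjusted p under 0.05. With the block it was 3032 and 3139 without unconverted 4sU A and B.

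After SLAM conversion 4 lists moved, each with 0 members called over all genes. Immediate-early genes had a median of 0.18 (camera adjusted p = 0.0245, and adjusted p = 0.763 with an estimated correlation), with 1 each way adjusted over the list alone. With the block 14 rose and 2 fell. Myc rose by 0.48 ± 0.064, Fosl1 by 0.38 and Klf2 by 0.70, whereas Klf6 fell by 0.47. Actin and SRF targets had a median of 0.21 (adjusted p = 0.0245, and adjusted p = 0.979 with an estimated correlation), with 5 higher adjusted over the list alone and 11 higher and 3 lower with the block. Actb rose from 3576 ± 252 to 5207 ± 525 CPM (0.54 ± 0.065, adjusted p = 1.53e-05), and Tagln2 (0.56), Zyx (0.56) and Tpm2 (0.32) also rose in that fit. Ribosomal protein genes had a median of 0.16 and ribosome biogenesis genes of -0.11 (both adjusted p = 0.0463, and adjusted p = 0.979 with an estimated correlation), with 0 adjusted over the list alone in each. With the block 18 ribosomal protein genes rose and 0 fell, among them Rpl19 (0.47), Rpl10a (0.38) and Rpl3 (0.32). Of 30 ribosome biogenesis genes 12 fell, including Utp20 (-0.45), Ddx21 (-0.40) and Gar1 (-0.52), and 2 rose, including Bop1 (0.36). The blocked test added nuclear noncoding RNAs (median -0.28, adjusted p = 0.048), the integrated stress response (0.11, adjusted p = 0.0281, 1 member higher over all genes and over the list alone) and glycolysis (0.16, adjusted p = 0.0423), in which Gapdh rose by 0.44 ± 0.077. All 3 lists lost the call with the block and an estimated correlation (adjusted p = 0.81 each). The p53 targets did not shift (median -0.05, adjusted p = 0.896).

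TUC conversion changed fewer genes past the threshold. Against unconverted 4sU RNA, edgeR's quasi-likelihood test called 0 genes, with 846 at an unadjusted p under 0.05, while DESeq2 called 15 (8 higher, 7 lower). Adding the letter as a block gave 3151 (1418 higher, 1733 lower), 194 of them past 1.5-fold. In that fit Dpysl2, a regulator of microtubule assembly in neurons, rose from 36.7 ± 0.746 to 76.3 ± 6.17 CPM (SD, n = 2; log2 fold change 1.06 ± 0.063, adjusted p = 1.63e-07, against adjusted p = 0.0785 without the block). The volume-regulated channel subunit Lrrc8a rose by 0.60, AI606181 by 0.94, Pin4 by 0.57, Med18 by 0.54, Ccdc85b by 0.53 and Nfia by 0.52. Zbed6 fell by 1.66 ± 0.207, Atp7a by 1.22, Zfp871 by 1.11, Lmbrd2 and Lnpep by 1.10 each, Pdpr and Lcor by 1.08 each and the kinase Hipk2 by 0.93. Myc (0.02), Cdkn1a (-0.01) and Mdm2 (-0.08) did not pass in either fit, whereas Actb (0.32) and Gapdh (0.24) rose with the block. With unconverted 4sU A, unconverted 4sU B, TUC A or TUC B left out the blocked counts were 661, 1132, 1226 and 568.

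Ribosomal protein genes had a median of 0.26 after TUC conversion (camera adjusted p = 1.22e-06, and adjusted p = 0.949 with an estimated correlation). Of 41 genes 0 passed over all genes or adjusted over the list alone, and 38 rose with the block, such as Rps23 (0.52), Rpl19 (0.36), Rpl7 (0.34) and Rpl14 (0.31). Oxidative phosphorylation genes had a median of 0.23 (adjusted p = 4.19e-08, and adjusted p = 0.949 with an estimated correlation), with 0 over all genes or over the list alone. With the block 24 of 32 rose, among them the complex IV subunits Cox5a (0.36 ± 0.06) and Cox5b (0.30) and the complex I subunit Ndufa1 (0.38). The effects of both chemistries, each taken within one letter against the unconverted library of that letter, could be compared without shared libraries. Across 10232 genes, which are not independent replicates, Pearson's r was 0.726 for SLAM A with TUC B and 0.465 for SLAM B with TUC A. It was 0.828 between the letters of SLAM and 0.783 between those of TUC.

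The direct comparison of TUC with SLAM libraries found 0 genes past the threshold by edgeR's quasi-likelihood test, with 1205 at an unadjusted p under 0.05. DESeq2 called 183 (78 higher in TUC, 105 lower), and with the letter as a block 2458 were called (1223 higher, 1235 lower), 181 past 1.5-fold. In the blocked fit Malat1 was at 795.6 ± 4.99 CPM in TUC and 266.8 ± 133 in SLAM libraries (SD, n = 2; log2 fold change 1.73 ± 0.203, adjusted p = 5.76e-05, against adjusted p = 0.436 without the block). By these SDs its letters lay apart in SLAM but close together in TUC. They therefore did not differ alike in both groups, as the block assumes. Trp53inp1 (0.76), Fam126b (0.75), the microRNA host gene Mir17hg (0.71), Mybl1 (0.71), Mzt1 (0.67), Tmem263 (0.67) and Cops9 (0.67) were also higher. Fam122a was lower by a log2 fold change of -1.30 ± 0.125, Rsc1a1 of -1.07, Zfp955a of -1.01, Ppp2r3d of -0.89, Ccdc85b of -0.88, Zbed5 of -0.87 and Zfpm1 of -0.79. The chaperone gene Hspa4 stood at 303.1 ± 61.9 CPM in TUC and 514 ± 3.89 in SLAM (-0.77 ± 0.079, adjusted p = 1.75e-05). Jun (-0.21) and Actb (-0.22) were lower in TUC with the block, while Gapdh (-0.20, adjusted p = 0.0761), Cdkn1a (0.07) and Mdm2 (0.13) did not pass. Leaving out TUC A or TUC B lowered the blocked count to 950 and 1025.

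Between the chemistries, 20 of 32 oxidative phosphorylation genes were higher in TUC with the letter as a block and 0 lower, including Ndufa1 (0.61 ± 0.077), Cox6c (0.60), Cox7c (0.52) and Atp5j2 (0.48). The list's median was 0.22 (camera adjusted p = 9.14e-08, and adjusted p = 0.945 with an estimated correlation), with 0 over all genes and 2 adjusted over the list alone. Immediate-early genes were lower in TUC, with a median of -0.13 (adjusted p = 0.0126, and adjusted p = 0.618 with an estimated correlation), 1 lower adjusted over the list alone, and 8 lower and 2 higher with the block. Myc (-0.46 ± 0.064), Klf2 (-0.65), Fosl1 (-0.38) and Klf4 (-0.24) were among the lower ones. Nuclear noncoding RNAs had a median of 0.28 (adjusted p = 0.0423, and adjusted p = 0.945 with an estimated correlation), with 0 over all genes or over the list alone. With the block 4 of 8 were higher, namely Malat1, Mir17hg, Neat1 (0.47 ± 0.124) and Snhg12 (0.32). In the blocked test ribosomal protein genes (median 0.08, adjusted p = 0.0125), fibroblast identity genes (-0.14, adjusted p = 0.0178) and actin and SRF targets (-0.12, adjusted p = 0.0356) passed too. With the block and an estimated correlation they lost the call (adjusted p = 0.867, 0.754 and 0.754). The p53 targets did not differ past the threshold (0.015, adjusted p = 0.833).

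Set against untreated cells, converted libraries carried both the 4sU and the chemistry. SLAM libraries differed in 2316 genes (930 higher, 1386 lower) and TUC libraries in 752 (164 higher, 588 lower) by edgeR's quasi-likelihood test, with 4366 and 3318 at an unadjusted p under 0.05. In SLAM libraries Fam122a rose by 1.74, Ccdc85b by 1.48, Zbed5 by 1.45, Cdkn1a by 1.41 ± 0.078, Psrc1 by 1.35, Phlda3 by 1.26, Cebpb by 1.23, Ttll3 by 1.17 and Gtse1 by 1.08. Dhx9 fell from 293.2 ± 49.7 to 96.6 ± 20.4 CPM (SD, n = 2; -1.60 ± 0.196, adjusted p = 0.00467). Zbed6 (-1.88), Nbeal1 (-1.67), Fam199x (-1.57), Phip (-1.57), Lnpep (-1.50), Dmxl1 (-1.49) and Ddx3y (-1.45) fell too. In TUC libraries Cdkn1a rose by 1.48 ± 0.078, Eda2r by 1.296, Btg2 by 1.28, Psrc1 by 1.27, Phlda3 by 1.19, Mdm2 by 1.08, the kinase Dyrk3 by 1.07 and Ddias by 1.03. Dhx9 (-1.62), Lmbrd2 (-1.53), Lnpep (-1.42), the DNA damage kinase gene Atm (-1.38), Rasa1 (-1.33), Epg5 (-1.32), the cohesin loader Nipbl (-1.29) and Pcm1 (-1.28) fell. The blocked fit called 7217 genes for SLAM (3568 higher, 3649 lower) and 6366 for TUC (3121 higher, 3245 lower), and DESeq2 3017 and 1685. A fit to only the 4 libraries of each comparison called 3 for SLAM and 152 for TUC. The SLAM count was 247 without untreated A, 172 without untreated B and 495 without SLAM A. The TUC count was 2 without untreated A, untreated B or TUC B, and 5 without TUC A.

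The p53 list was higher in both, with 15 of 26 genes higher and 1 lower for SLAM (16 and 1 adjusted over the list alone) and 12 higher and 0 lower for TUC (17 and 1 over the list alone). Medians were 0.49 (camera adjusted p = 1.18e-06, and adjusted p = 0.0619 with an estimated correlation) and 0.51 (adjusted p = 5.82e-10, and adjusted p = 0.0267 with an estimated correlation). With the letter as a block and an estimated correlation the TUC value was adjusted p = 0.112. Ribosomal protein genes had medians of 0.38 and 0.47 (adjusted p = 0.000106 and 5.42e-09, and adjusted p = 0.812 and 0.709 with an estimated correlation). Of 41 genes 38 rose for SLAM and 41 for TUC with the block, against 1, Rpl10a (0.71 ± 0.154), and 0 without, and 0 in each adjusted over the list alone. Oxidative phosphorylation genes passed for TUC, with a median of 0.42 (adjusted p = 5.82e-10, and adjusted p = 0.659 with an estimated correlation). There 2 rose, Cox5a (0.49) and Ndufa1 (0.48), 25 rose adjusted over the list alone, and 32 of 32 with the block. For SLAM, immediate-early genes had a median of 0.27 (adjusted p = 0.00142, and adjusted p = 0.188 with an estimated correlation), with 6 higher and 1 lower over all genes and over the list alone. Fosl1 rose by 0.54, Ier5 by 0.39 and Btg2, also in the p53 list, by 0.98, and Klf6 fell by 0.49. Actin and SRF targets had a median of 0.33 (adjusted p = 0.0108, and adjusted p = 0.425 with an estimated correlation), with 6 of 19 higher over all genes and over the list alone, such as Tagln2 (0.70), Zyx (0.62), Acta2 (0.55) and Tpm2 (0.53). The blocked test added, for SLAM, short-lived regulators (median 0.26, adjusted p = 0.0342), the integrated stress response (0.20, adjusted p = 0.0145), oxidative phosphorylation (0.21, adjusted p = 0.0206), glycolysis (0.23, adjusted p = 0.0342) and fibroblast identity (0.25, adjusted p = 0.0437). For TUC it added the integrated stress response (0.17, adjusted p = 0.0377), and all of these lost the call with an estimated correlation (smallest adjusted p = 0.622).

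The share of newly made RNA spanned nearly the whole scale in converted libraries. Ptgs2, Nuak2, Rgs16, Rpusd2, Dyrk3, Bdnf, Cwc22 and F3 had a mean NTR of 1.0 in SLAM libraries, the upper end of the scale. At the other end stood Pltp, a phospholipid transfer protein (0.036 ± 0.0028; SD, n = 2), the surface antigen Ly6a (0.036), Gchfr (0.036), Gstm2 (0.041) and the complement proteases C1s1 (0.036), C1ra (0.040) and C1rb (0.041). By list, the median NTR in SLAM libraries was 0.987 for immediate-early genes, 0.973 for NF-kB inflammatory genes, 0.971 for short-lived regulators and 0.844 for p53 targets. It was 0.614 for G2/M genes, 0.248 for fibroblast identity, 0.205 for glycolysis, 0.139 for ribosomal proteins and 0.125 for oxidative phosphorylation. Cdkn1a stood at 0.994 ± 0.0069, Mdm2 at 0.997, Myc at 0.987, Jun at 0.948, Actb at 0.445 and Gapdh at 0.146 in SLAM libraries. The corresponding TUC values were 0.980, 0.993, 0.975, 0.955, 0.499 and 0.151. Over 9956 genes with 100 or more reads in each converted library, the median NTR was 0.520 in SLAM A, 0.609 in SLAM B, 0.541 in TUC A and 0.627 in TUC B. NTR was higher in B than in A for 85.3% of genes in SLAM and 85.5% in TUC libraries.

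TUC and SLAM ranked genes by NTR almost alike, with a Spearman rho across genes of 0.993 in letter A and 0.992 in letter B, against 0.989 and 0.99 between letters within SLAM and TUC. Genes are not independent replicates. The median difference of TUC minus SLAM was 0.00965 (0.0104 in A and 0.0089 in B). Leaving out a library, which leaves the letters unbalanced, turned or raised it: -0.0124 without SLAM A, -0.0115 without TUC B, 0.036 without SLAM B and 0.035 without TUC A. limma on logit NTR with Benjamini-Hochberg adjustment called 14 genes, 8 higher and 6 lower in TUC, with 249 at an unadjusted p under 0.05. Naaa, a lysosomal acid amidase (0.042 ± 0.0029 in SLAM, 0.093 ± 0.0059 in TUC; SD, n = 2; limma adjusted p = 0.00555), Ly6c1 (0.025 and 0.051), Aldh6a1 (0.038 and 0.075) and Fam122a (0.913 and 0.988) were higher in TUC. Lower in TUC were the translation termination factor Gspt2 (0.988 and 0.902, limma adjusted p = 0.00205), the forkhead factor Foxo1 (0.990 and 0.932), Rasl11a (0.977 and 0.907), Kank1 (0.990 and 0.927), Tyw3 (1.0 and 0.945) and Zbtb5 (1.0 and 0.962). SLAM values of 1.0 were set just below the end of the scale for the test and then have no spread. With the letter as a block limma called 0 genes, with 1152 at an unadjusted p under 0.05, and adjusted p of the named genes lay between 0.427 and 0.439. The count was 68 without SLAM A (16 higher, 52 lower), 142 without SLAM B (21 higher, 121 lower), 198 without TUC A (33 higher, 165 lower) and 152 without TUC B (69 higher, 83 lower). The balance of directions was not stable to the read minimum either, with 4 higher and 10 lower at 500 reads or more.

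Counts in converted libraries fell with rising NTR. In 5 equal bins of 10232 genes ranked by SLAM NTR, the median log2 fold change of SLAM against unconverted 4sU went from 0.14 in the bin of lowest NTR through 0.06, -0.03 and -0.10 to -0.16 in the highest. For TUC it went from 0.16 to -0.10. In the highest bin of 2047 genes, 847 fell and 202 rose in SLAM and 534 fell and 54 rose in TUC with the letter as a block. In the lowest bin 145 fell and 851 rose, and 103 fell and 750 rose. The highest bin shifted down by camera (p = 2.37e-08 for SLAM and 9.53e-08 for TUC, and p = 0.256 and 0.275 with an estimated correlation). TUC against SLAM went from -0.02 to 0.04 (highest bin p = 0.0243, and p = 0.627 with an estimated correlation). This trend came from letter A (-0.038 in the lowest and 0.077 in the highest bin), while in letter B both ends were alike (0.008 and 0.010). Against untreated cells the highest bin had a median of -0.15 in SLAM and -0.11 in TUC (p = 0.000264 and 0.00325, and p = 0.44 and 0.529 with an estimated correlation). The fourth bin lay lower, at -0.179 and -0.157. With NTR ranked within bins of gene length the highest bin did not pass (-0.0798 and -0.0371, camera p = 0.062 and 0.383 at the preset correlation). Unconverted 4sU against untreated gave 0.12, 0.02, -0.06, -0.08 and 0.001 from low to high, and the highest bin did not shift by camera with its preset correlation (p = 0.521). The lowest bin shifted up (camera p = 6.39e-12, and p = 0.172 with an estimated correlation). Against uridine the highest bin had a median of 0.010 (p = 0.462 at the same preset correlation). The lowest bin there had 0.115 (camera p = 7.54e-10, and p = 0.213 with an estimated correlation). In the top 10% by NTR, however, the medians were 0.029 against untreated and 0.032 against uridine, which passed (p = 0.015 and 0.0373 at that correlation), and TUC against untreated no longer passed (-0.081, p = 0.115). Uridine against untreated gave 0.008 in the lowest and -0.002 in the highest bin (p = 0.861 at the same correlation).

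**Figure D2:**
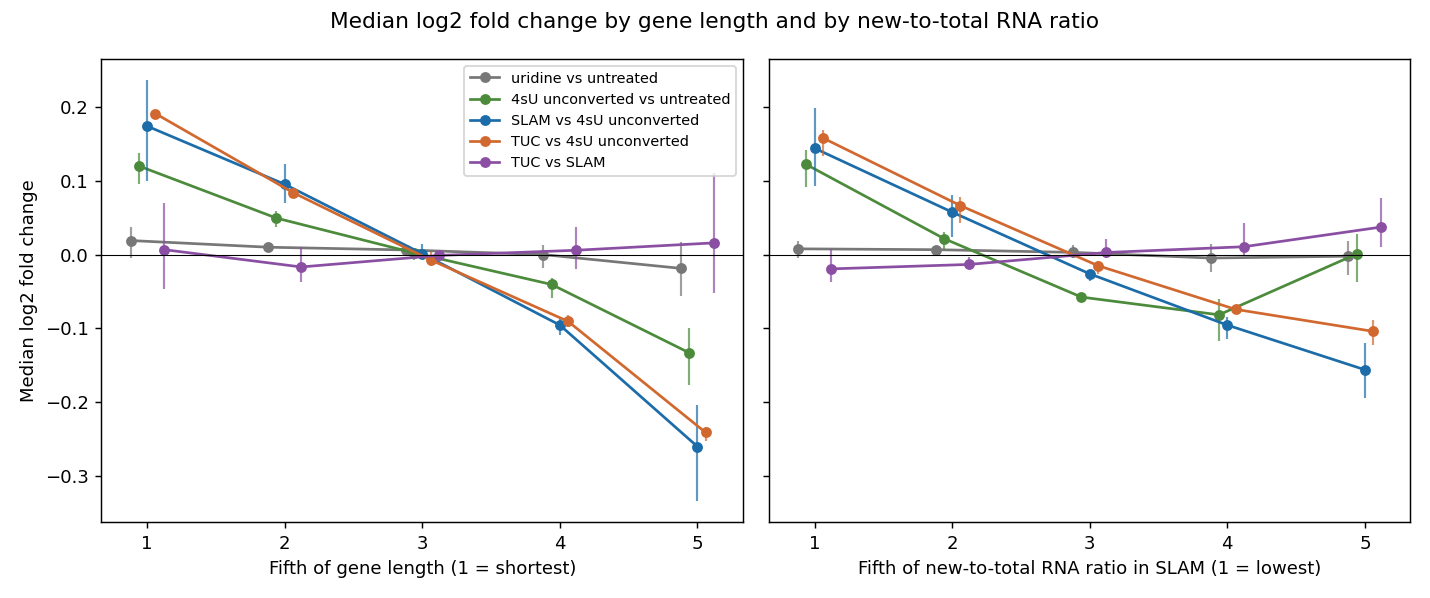
Median log2 fold change in 5 equal bins of genes ranked by NTR and in 5 equal bins ranked by gene length; points are medians over all genes of a bin and vertical bars span the values of letters A and B. SLAM against unconverted 4sU runs from 0.14 to -0.16 over the NTR bins and from 0.17 to -0.26 over the length bins.

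The same comparisons also changed with gene length. From the shortest to the longest of 5 bins, the median log2 fold change went from 0.17 to -0.26 for SLAM and from 0.19 to -0.24 for TUC against unconverted 4sU. In unconverted 4sU against untreated it went from 0.12 to -0.13. The shortest bin (up to 2019 bases) had 0.106 in unconverted 4sU against uridine, and 0.286 and 0.311 in SLAM and TUC against untreated. The median lengths of the oxidative phosphorylation and ribosomal protein lists, 783 and 1248 bases, fall in that bin. Whether these lists moved beyond it was not tested with length-matched lists. Between TUC and SLAM, where oxidative phosphorylation genes had 0.218, the shortest bin had 0.007. In the longest bin 1279 genes fell and 79 rose in SLAM, and 1188 fell and 29 rose in TUC, with the letter as a block. Spearman's rho across genes between fold change and length was -0.562 for SLAM, -0.723 for TUC, -0.472 for unconverted 4sU against untreated and 0.0305 for TUC against SLAM. Within 10 bins of length, rho between fold change and NTR was -0.287 for SLAM and -0.331 for TUC, against -0.394 and -0.447 over all genes. For unconverted 4sU against untreated it was -0.135 within bins of length and -0.273 over all genes. Within 10 bins of NTR, rho between fold change and length was -0.483 for SLAM and -0.673 for TUC, so more of the length relation was kept. For TUC against SLAM the letters ran in opposite directions, from -0.047 in the shortest to 0.11 in the longest bin in A and from 0.070 to -0.052 in B, and cancelled in the medians of both together (0.007 and 0.016).

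Per library, the median of high-NTR minus low-NTR genes (log2 CPM centred per gene) was 0.110 and 0.252 in untreated A and B, 0.070 and 0.276 with uridine, -0.059 and 0.188 with unconverted 4sU, -0.447 and -0.017 with SLAM and -0.345 and -0.033 with TUC. The mean of the 6 libraries with 4sU differed from that of the 4 without by -0.296, although unconverted 4sU B lay above untreated A and uridine A. The difference did not pass a two-sided exact permutation test (p = 0.0524 over 210 splits, smallest possible p 0.0048). Permuted within letters (the replicate block), the exact permutation p was 0.02 over 100 arrangements. Both tests count each library as independent. The labels do not say whether 4sU libraries of one letter came from the same RNA, in which case neither p would hold. With NTR ranked within bins of gene length the difference shrank to -0.155 (exact permutation p = 0.0714, and 0.02 within letters). Without unconverted 4sU B the difference was -0.358 and the exact permutation p was 0.0159.

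The loss of new RNA that would remove the relation between NTR and the ratio to untreated libraries, called 4sU dropout, was 30.6 ± 18.1% in SLAM libraries (SD, n = 2; 43.4 in A and 17.8 in B). It was 29.0 ± 13.5% in TUC (38.6 and 19.5), 10.7 ± 14.4% in unconverted 4sU (20.9 and 0.49) and 1.02 ± 13.1% in uridine libraries (10.3 and -8.26). The means of TUC and SLAM differed by less than the SD of either group, and no test was run on dropout. With the untreated library of the same letter as reference, a block on the letter, dropout was 31.4 ± 12.1% in SLAM, 29.7 ± 6.51% in TUC, 11.4 ± 6.43% in unconverted 4sU and 1.3 ± 4.31% in uridine libraries. Within 10 bins of gene length it was 18.4 ± 12.2% in SLAM, 15.2 ± 10.7% in TUC and 4.8 ± 8.62% in unconverted 4sU libraries (10.9 in A and -1.29 in B).

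**Figure D3:**
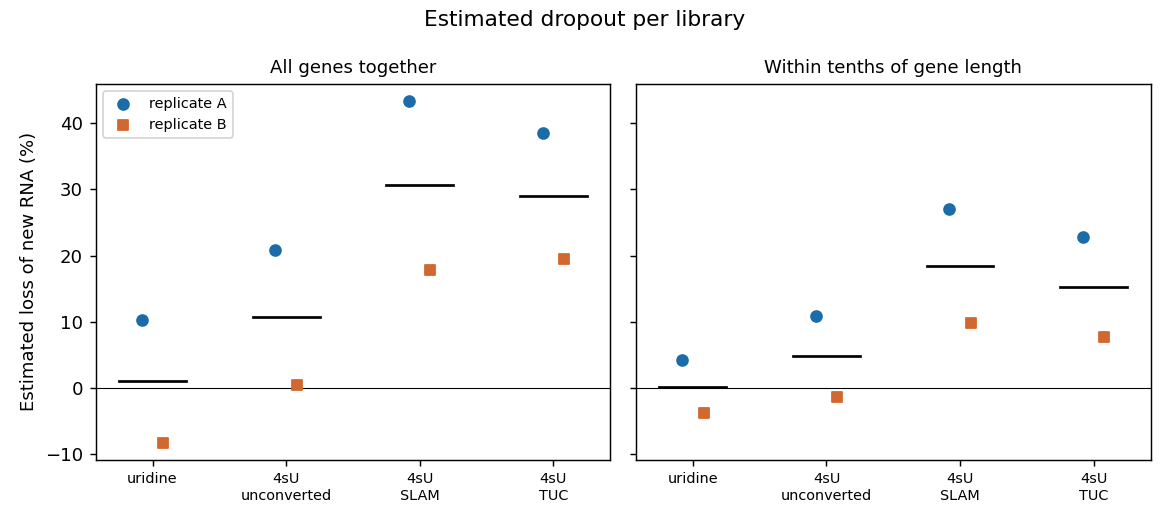
Estimated 4sU dropout in percent for uridine, unconverted 4sU, SLAM and TUC libraries; bars are group means and points are libraries A and B. SLAM libraries lie at 43.4 and 17.8% and TUC libraries at 38.6 and 19.5%.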

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

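Of the tests in this part, only the letter block combined with an estimated correlation was chosen after these results had been seen. Counts of nuclear oxidative phosphorylation genes drew attention because they differed between the 2 chemistries, with a median log2 fold change of 0.218 in TUC against SLAM libraries, although both act on RNA from cells given the same label. Immediate-early genes differed the other way (-0.134), and nuclear noncoding RNAs were higher in TUC (0.283), led by Malat1. All 3 shifts lost the call with an estimated correlation between genes. With the letter as a block and an estimated correlation, 0 lists passed between the chemistries.

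Libraries with 4sU but no conversion had a median NTR of 0.0194 (A) and 0.0177 (B), above that of uridine libraries (0.0142 and 0.010). Across genes, the lowest Spearman rho of their NTR with that of a converted library was 0.459, where uridine libraries gave 0.0843 to 0.0969. These values were not taken further.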

How the results depend on the processing

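No gene past the threshold without the block turned direction in any setting run for it, where leaving out a library was run only for the comparisons that use it. Among genes not past it, Gapdh for uridine changed from -0.004 to 0.001 with the block. More than its error separated the turned value from the first one in 3 results without untreated A, 2 without SLAM A and 2 without TUC B, the last including Neat1 between TUC and SLAM (-0.908). With the letter as a block 116 of 280 gene results stayed on their side of the threshold and 164 gained a call. Part of the 280 were named because they passed with the block, so these gains follow partly from that choice. With DESeq2 214 of the gene results stayed and 66 gained a call. By camera the block changed no other call of a list or bin than those given beside the results. By fry with the block further lists passed. Between TUC and SLAM they included cholesterol synthesis (fry adjusted p = 0.0335) and histones (0.0475). For SLAM against unconverted 4sU they included cholesterol synthesis (fry adjusted p = 0.0164) and NRF2 targets (0.0377). The p53 targets passed in neither (fry adjusted p = 0.282 and 0.13). RLE factors ended 5 calls and added 1, library totals ended 16, no filter ended 2 and added 14, and a mean of 100 counts ended 2 and added 1 of 272, while a fit to only the 4 libraries of a comparison ended 74 and added 1. The cause of these changes was not tested except where fewer libraries or a smaller dispersion (0.00195 with the block, 0.0187 without) follow from the setting. The conversion rate per library was not run. The block combined with other settings, and ranking within bins of gene length, were chosen after the data were seen.

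With the replicate block the counts of called genes were 1 for uridine against untreated, 2432 for unconverted 4sU against untreated, 2412 against uridine, 5079 for SLAM and 3151 for TUC against unconverted 4sU, 2458 for TUC against SLAM, and 7217 for SLAM and 6366 for TUC against untreated. From the second of these on, the block with library totals gave 2171, 2200, 4903, 2742, 2239, 7048 and 6104, and the block with a mean of 100 counts or more gave 2520, 2529, 4985, 3203, 2428, 6850 and 6235. For uridine against untreated both gave 0. DESeq2 gave 241 and 275 for unconverted 4sU against untreated and uridine, 693 for SLAM and 15 for TUC against unconverted 4sU, 183 for TUC against SLAM and 1685 for TUC against untreated. Only the 4 libraries gave 1, 0 and 0 for unconverted 4sU against untreated, against uridine and for SLAM against unconverted 4sU, and 3 and 152 for SLAM and TUC against untreated. For SLAM against unconverted 4sU, library totals gave 22 and a mean of 100 counts 27. Without a count filter TUC gave 2 against unconverted 4sU and 2 against SLAM.

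Leave-one-out counts ranged from 2 to 3 for unconverted 4sU against untreated, 1 to 2 against uridine, 172 to 2882 for SLAM and 2 to 5 for TUC against untreated. They were 0 to 0 for uridine against untreated, SLAM against unconverted 4sU, TUC against unconverted 4sU and TUC against SLAM. With the block they ranged from 0 to 1 for uridine and 890 to 1996 for unconverted 4sU against untreated, 929 to 1042 for unconverted 4sU against uridine, 3032 to 5703 for SLAM and 568 to 1226 for TUC against unconverted 4sU, 950 to 2997 for TUC against SLAM, and 5796 to 7364 for SLAM and 4651 to 5708 for TUC against untreated. For TUC against SLAM by NTR they ranged from 68 to 198.

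The high minus low NTR shift was -0.306 with TUC values (exact permutation p = 0.0476), -0.3242 with 500 reads (exact p = 0.0429), -0.2959 with the replicate block (exact p = 0.02), -0.1548 with ranking within gene length (exact p = 0.0714) and -0.1548 with both (exact p = 0.02). Leave-one-out values ranged from -0.3577 to -0.2281, with exact p from 0.0159 to 0.0952. For the highest NTR bin, the top 10% gave 0.0291 (p = 0.015 at the preset correlation) and 0.0324 (p = 0.0373) for unconverted 4sU against untreated and uridine, and -0.0813 (p = 0.115) for TUC against untreated. With an estimated correlation SLAM and TUC against unconverted 4sU were -0.156 (p = 0.256) and -0.104 (p = 0.275), TUC against SLAM 0.0373 (p = 0.627), and SLAM and TUC against untreated -0.154 (p = 0.44) and -0.107 (p = 0.529). With the replicate block and an estimated correlation the same 5 were -0.159 (p = 0.193), -0.104 (p = 0.193), 0.0382 (p = 0.582), -0.156 (p = 0.337) and -0.107 (p = 0.395). With the replicate block at the preset correlation the medians were -0.00384 for uridine and -0.00117 for unconverted 4sU against untreated, 0.00978 for unconverted 4sU against uridine, -0.159 and -0.104 for SLAM and TUC against unconverted 4sU, 0.0382 for TUC against SLAM, and -0.156 and -0.107 for SLAM and TUC against untreated. Ranked within gene length, SLAM and TUC against unconverted 4sU gave -0.105 (p = 0.000208 at the preset correlation) and -0.0548 (p = 0.00361), and against untreated -0.0798 (p = 0.062) and -0.0371 (p = 0.383). Dropout within bins of gene length was 15.2% in TUC and 4.8% in unconverted 4sU. The NTR test of TUC against SLAM called 0 genes with the replicate block, 2 on the untransformed scale and 0 with both.

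Gene lists past the threshold numbered 0 for uridine and 7 for unconverted 4sU against untreated, 6 for unconverted 4sU against uridine, 4 for SLAM and 2 for TUC against unconverted 4sU, 3 for TUC against SLAM, and 4 for SLAM and 3 for TUC against untreated. With an estimated correlation these were 0, 1, 1, 0, 0, 0, 0 and 1, and with the block as well 0, 1, 1, 0, 0, 0, 0 and 0. The replicate block at the preset correlation gave 0, 8, 7, 7, 2, 6, 9 and 4. By fry without the block 3 lists passed for unconverted 4sU against untreated, 3 against uridine, and 0 for SLAM against unconverted 4sU, TUC against unconverted 4sU and TUC against SLAM. Leave-one-out ranges in the same order were 3 to 5, 6 to 8, 4 to 8, 3 to 5, 2 to 4, 3 to 7, 5 to 7 and 5 to 8. Uridine against untreated had 5 without untreated A, 3 without untreated B, 4 without uridine A and 4 without uridine B. TUC against unconverted 4sU had 4 without unconverted 4sU A, and TUC against SLAM 6 without TUC A and 7 without TUC B. SLAM against untreated had 7 without SLAM B, and TUC against untreated 5 without untreated A, 6 without untreated B, 8 without TUC A and 5 without TUC B.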

Other observations

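Many genes differed between the replicate letters, a comparison that was made only after the data had been seen. With the letter in the fit (5 libraries per letter), Ly6c1 stood at 18.5 ± 1.5 CPM in B and 4.40 ± 0.774 in A (SD, n = 5; log2 fold change 2.08 ± 0.069, edgeR adjusted p = 4.68e-12). The 5 libraries of a letter come from the 5 groups, so the SD spans the treatments. The labels do not say whether they share a culture or RNA. If they do, they are not independent replicates, and the p-values and counts between letters would not hold. Neat1, the scaffold of paraspeckles, was higher in B by 1.78 ± 0.081, the matrix protein Prelp by 1.82, Wisp2 by 1.71 and the orphan receptor Nr4a3 by 1.68. Postn, which encodes the matrix protein periostin, stood at 72.8 ± 5.57 CPM in B and 179 ± 18.1 in A (-1.29 ± 0.048), and Vip (-1.46), Cth (-1.13) and Pck2 (-0.94) were lower in B too. In all 7368 genes differed, 3790 higher and 3578 lower in B, 669 of them past 1.5-fold.

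Among lists, 41 of 41 ribosomal protein genes were lower in B (median -0.34, camera adjusted p = 6.85e-13, and adjusted p = 0.378 with an estimated correlation). Of the integrated stress response genes 21 were lower and 3 higher (-0.44, adjusted p = 3.91e-07, and adjusted p = 0.275 with an estimated correlation). G2/M genes had 19 lower and 0 higher (-0.32, adjusted p = 5.55e-07, and adjusted p = 0.275 with an estimated correlation). The p53 targets (0.046, adjusted p = 0.401) and fibroblast identity genes (0.002, adjusted p = 0.924) did not shift. What the letters share is not stated in the labels.

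For the p53 targets, the test of all libraries was chosen only after the result was seen. Lists matched to them on NTR and count had a mean median log2 fold change of -0.0166, and lists matched on gene length and count of 0.0164, against 0.494 for the p53 list. Neither a shift of highly labelled transcripts as a class nor length therefore accounts for the rise. The lowest library with 4sU stood at 0.15 on the list's centred log2 CPM, above the highest without at -0.224, an order already visible in the comparisons from which the pattern came, so a response of the cells to 4sU stays open.

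Genes named as pseudogenes had a median of 0.264 after SLAM conversion (14 genes, 2 called, camera p = 0.00442, and p = 0.389 with an estimated correlation). They were not among the lists fixed beforehand and were taken up as a pattern in these data, so their camera p-values are no independent test. The predictions of the tests of both explanations below were written before those test results were seen. In TUC against the same unconverted libraries the median was 0.353 (0 called, 11 higher and 1 lower with the block, camera p = 8.39e-07, and p = 0.164 with an estimated correlation), and in unconverted 4sU against untreated 0.187 (0 called, camera p = 0.0572, and p = 0.557 with an estimated correlation). Their fold change in SLAM had a Spearman rho of -0.00825 with the NTR of the parent gene (13 genes, permutation p = 0.98), so whether reads shared with the parent play a part cannot be told apart from no relation. Lists matched on gene length and count had a mean median of 0.144, with the pseudogenes at percentile 96.27, so short length or low count may account for the shift.

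For the fall of counts with NTR after conversion, the test of letters was chosen only after the result was seen. Within 10 bins of gene length rho was -0.287 for SLAM and -0.331 for TUC, so length did not account for the whole relation. Within 10 bins of NTR, rho of the fold change with length was -0.483 and -0.673, so NTR did not account for the length relation either. Letter A had the larger dropout and the lower NTR in both chemistries, with a median odds ratio of NTR of A over B of 0.74 in SLAM and 0.751 in TUC, as a loss of labelled RNA would give. Dropout was also estimated larger in A in uridine libraries (10.3 and -8.26%) and in unconverted 4sU (20.9 and 0.49%), so such a loss cannot be told apart from whatever else the letters differ in. Against the untreated library of the same letter, A and B lay closer but in the same order. Values were 4.35 and -1.74% in uridine, 15.9 and 6.81% in unconverted 4sU, 39.9 and 22.8% in SLAM and 34.3 and 25.1% in TUC. No biological explanation was tested.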
